A study of Mus musculus with 21 samples.

How the data were processed

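RNA of mouse cerebellar cells and of cerebellar tumours was sequenced in 21 libraries. Sox2+ cells and Math1+ cells had been sorted by GFP from reporter mice in the early postnatal period, and tumours had been grown from such cells after infection with a Myc lentivirus and injection into the cerebellum of immunodeficient mice, per the labels. The libraries formed 4 groups: Sox2+ normal cells (n = 3), Math1+ normal cells (n = 3), SOX2 tumours (n = 8) and MATH1 tumours (n = 7). The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical for the normal cells. The labels also do not say whether the tumour cells were sorted before RNA isolation.

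The authors deposited FPKM values per gene symbol (fragments per kilobase of gene length, scaled to library size) in a table of 30808 symbols with 1 column per library. Per the submitters' processing notes, CASAVA 1.8.2, HISAT2, HTSeq 0.6.1 and DESeq2 were used with the GRCm38 build. Their roles, the annotation, the definition of gene length and the use of strand are not given in the sources used here. Of the symbols, 29439 (95.6%) matched GENCODE M21 on GRCm38, which supplied coordinates and gene types. The table held 24 symbols that a spreadsheet had turned into dates, and 4 entries with a repeated symbol were left out. Each of the 21 columns was mapped to its sample by name, and 0 columns belonged to no sample.

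Depth was estimated from the low values. Each library was compared with Normal_M4, which had the most genes above 0. Below 0.05 FPKM, 84.7% to 95.4% of the ratios of a gene's values lay within 0.01 of a ratio of small whole numbers (denominators up to 6). Values made from whole reads do so, but the share that chance would give was not estimated. The value of 1 read then implied totals of 12.7 M to 52.1 M reads per library, so that 1 FPKM of a gene of 2 kb stood for 25.4 to 104.2 reads. Because counts were not used, each test ran on log2(FPKM + 1), and fold changes are on that scale, which understates the change of genes with low values.

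Differences between groups were tested with limma 3.58.1 in R 4.3.3 (linear model, eBayes with a mean-variance trend, two-sided) on genes with at least 1 FPKM in at least 3 libraries of the fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene passed when its adjusted p lay under that threshold. The pairwise comparisons used only the groups compared. The difference between the tumour-against-normal changes of both origins was an interaction term over all 4 groups. The similarity of tumours was compared with an exact permutation test over all splits into groups of 8 and 7, and the relation of normal to tumour differences with 100 permutations of the tumour labels. In total 26 gene lists with 502 genes (8 of them not in the table) covering cell types, tumour subgroups and pathways were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and by ranks, wherever at least 3 members were measured, which held for 24 lists in at least 1 comparison. Members were counted as passing over all genes tested and adjusted over the list alone. Groups, tests, gene lists, the rule for named genes and all alternatives but those said below to have been added were fixed before the data were examined.

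Genes were named by that rule: Myc, Mycn, Sox2, Atoh1, Gfap, Gli1, Npr3 and Otx2 whatever their result, up to 2 members with the largest change of each list with at least 25% of its measured members passing, and the 5 highest and 5 lowest changes among passing genes with a mean of at least 10 FPKM in the higher group and no overlap between libraries (for the interaction, at least 10 FPKM in any group and no overlap condition). Some genes that met the rule are not reported here. Any other gene named was chosen after its values were seen.

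On simulated data in which 200 genes were changed by a log2 value of 1 or 2 up or down, the test recovered 97% and 100% of the changed genes between normal groups and 91% and 98% between tumours. It recovered 85% and 95% for SOX2 tumours against Sox2+ cells, 87% and 97% for MATH1 tumours against Math1+ cells, and 73% and 90% for the interaction. False calls made up 7.1%, 3.6%, 6.2%, 7.5% and 4.7% of all calls in these comparisons, in the same order. The changed genes were drawn only from genes with mean values well above the filter, and the noise was normal and independent between genes. All groups of a comparison were given the same spread per gene, although real tumours varied more than normal cells. These rates may therefore not hold for genes of low value or for genes that vary together. They may also not hold for the comparisons of tumours with normal cells and the interaction.

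Alternatives to the main choices were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, quantile normalization, array weights, eBayes without trend, all 4 groups in 1 fit, a minimum log2 change of 1, a replicate block for the normal cells and leaving out each library in turn. After the data had been seen, fits without pseudogenes and their parent genes, and fits without the tumour libraries with the lowest correlation to their own group, were added. Parent genes of pseudogenes were found by aligning GENCODE M21 transcripts to each other with BLASTN 2.17.0 (at least 90% identity over 200 bases). Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

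No pair of libraries of a group agreed within sampling noise: the median ratio of the squared difference to that of counting noise was 1.77 to 4.67 among Math1+ cells, 2.49 to 3.34 among Sox2+ cells, 5.68 to 30.0 among SOX2 tumours and 10.8 to 39.4 among MATH1 tumours. This excludes 1 set of reads listed under 2 titles, but not 2 libraries from 1 animal; all 21 were used as replicates because the labels list them so.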

Results

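The study asked how tumours driven by Myc resemble or differ from each other when they arise from different cells of the postnatal cerebellum. Cells that express Sox2, a transcription factor of neural stem cells and glia, and cells that express Math1 (the product of Atoh1), a factor of granule neuron progenitors, were sorted as GFP+ cells. Both kinds were also the starting cells of tumours made by infection with Myc lentivirus and injection into the cerebellum. RNA was sequenced from 3 libraries of Sox2+ cells, 3 of Math1+ cells, 8 SOX2 tumours and 7 MATH1 tumours. The deposited values implied totals of 19 M to 31.2 M reads for Sox2+ cells, 15.7 M to 52.1 M for Math1+ cells, 14.3 M to 15.9 M for SOX2 tumours and 12.7 M to 15 M for MATH1 tumours. Between 10068 and 11293 genes reached 1 FPKM in a library. Mitochondrial genes took 11.93 ± 1.01% of all FPKM in MATH1 tumours, 7.38 ± 1.48% in SOX2 tumours, 6.97 ± 0.51% in Math1+ cells and 6.37 ± 0.45% in Sox2+ cells (mean ± SD). Ribosomal protein genes took 6.69 ± 0.77%, 6.50 ± 0.34%, 3.33 ± 0.15% and 2.43 ± 0.06% in the same order. Values of genes are FPKM as mean ± SD over the libraries of a group (n = 3 for each kind of normal cell, n = 8 SOX2 tumours, n = 7 MATH1 tumours). Changes are differences of mean log2(FPKM + 1), and p-values are limma's, adjusted over all genes tested.

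The normal cells separated from each other more than the tumours did. Libraries of normal cells correlated with a mean Pearson r of 0.990 within Sox2+ cells, 0.992 within Math1+ cells and 0.852 between them, over 13059 genes, which are not independent replicates. SOX2 tumours correlated with MATH1 tumours at 0.924, close to the 0.946 within SOX2 tumours and 0.935 within MATH1 tumours. SOX2 tumours correlated at 0.793 with Sox2+ cells and at 0.843 with Math1+ cells, and MATH1 tumours at 0.767 and 0.841. Among the tumours, named here by their titles, the SOX2 tumour Sox2_727 (mean r of 0.911 to its own group) and the MATH1 tumour Math1_1065 (0.894) stood farthest from their groups.

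**Figure D1:**
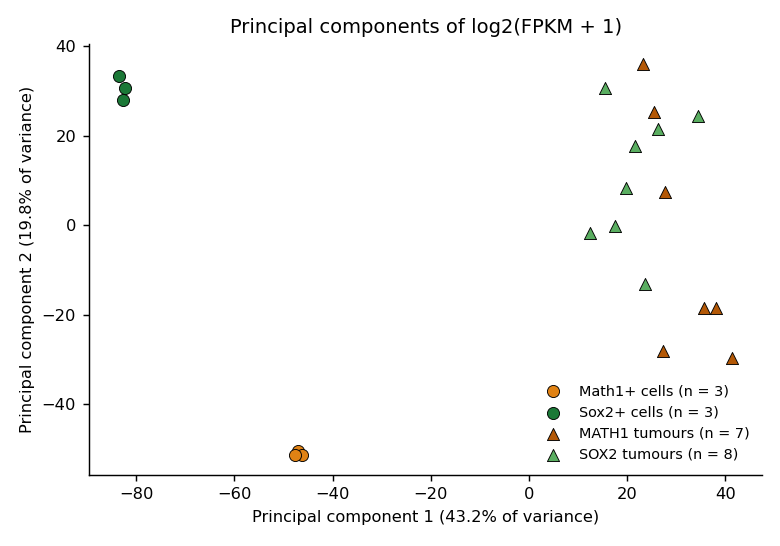
Principal components of log2(FPKM + 1) over 13059 genes, with 1 point per library (circles, normal cells; triangles, tumours). The first component took 43.2% and the second 19.8% of the variance, and the tumours of both origins lay nearer to each other than the normal groups did.

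Sox2+ and Math1+ normal cells were compared to describe the starting populations. Sox2+ cells had higher levels of genes of astrocytes and Bergmann glia, of neural stem cells, of the oligodendrocyte lineage and of the GABAergic lineage of the cerebellum, while Math1+ cells had higher levels of most granule neuron progenitor genes, Sonic hedgehog targets and cell cycle genes. None of the list calls held with an estimated correlation (adjusted p from 0.397 to 0.424). The genes that defined the sorts separated the groups: Sox2 (chromosome 3, 34650405 to 34652461, GRCm38), a transcription factor of neural stem cells, was 60.4 ± 4.09 in Sox2+ and 1.71 ± 0.556 in Math1+ cells (log2 difference 4.52, adjusted p = 2.96e-07). Atoh1 (chromosome 6, 64729125 to 64731245), which specifies granule neuron progenitors, was 3.73 ± 1.87 and 78.7 ± 5.90 (log2 difference -4.14, adjusted p = 5.32e-06). The astrocyte filament gene Gfap (chromosome 11, 102887336 to 102900912) was 53.4 ± 10.5 in Sox2+ and 1.23 ± 0.493 in Math1+ cells (4.61, adjusted p = 8.51e-07).

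Of 30 measured genes of astrocytes and Bergmann glia, 29 were higher in Sox2+ cells and 1 was lower (30 passed when adjusted over the list alone, camera adjusted p = 1.97e-12, adjusted p = 0.397 with an estimated correlation). The highest differences of the comparison were among them: the water channel gene Aqp4 (chromosome 18, 15389496 to 15410982) was 186 ± 35.9 against 1.17 ± 0.779, the growth factor gene Gdf10 (chromosome 14, 33923587 to 33937983) 250 ± 40.8 against 2.10 ± 0.808, and Sparcl1, which encodes a secreted matrix protein, 575 ± 66.4 against 6.05 ± 0.755 (log2 differences 6.47, 6.36 and 6.35). The glial receptor gene Gpr37l1 was 141 ± 26.5 against 0.854 ± 0.564, and the exception was Sox9, with a log2 difference of -0.39. Of 15 neural stem and radial glia genes, 13 were higher and 2 lower (15 when adjusted over the list alone, camera adjusted p = 0.000115, adjusted p = 0.397 with an estimated correlation). An example was Sox1 at 51.1 ± 3.88 against 0.685 ± 0.260. Of 16 oligodendrocyte lineage genes, 15 were higher and Pdgfra lower (16 when adjusted over the list alone, camera adjusted p = 1.06e-06, adjusted p = 0.424 with an estimated correlation), led by Gpr17 (71.9 ± 15.3 against 0.438 ± 0.198) and Olig1 (chromosome 16, 91269772 to 91271933), at 84.3 ± 18.3 against 1 ± 0.681. Of 13 GABAergic lineage genes, 12 were higher and Lhx1 lower (13 when adjusted over the list alone, camera adjusted p = 3.64e-06, adjusted p = 0.397 with an estimated correlation). Among them was the transcription factor gene Lhx5 (chromosome 5, 120431699 to 120441223), at 172 ± 15.5 against 1.21 ± 0.425. Choroid plexus and ependyma genes were also higher (6 of 7, with Otx2 lower, 7 when adjusted over the list alone, camera adjusted p = 0.0292, adjusted p = 0.397 with an estimated correlation). Examples were the ciliary regulator Foxj1 at a log2 difference of 2.80 and Enpp2 at 2.79.

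Math1+ cells had higher levels of 38 of 38 proliferation genes (38 when adjusted over the list alone, camera adjusted p = 6.98e-11, adjusted p = 0.397 with an estimated correlation). Examples were E2f1 at 44.2 ± 5.03 against 13.9 ± 0.348 and the replication helicase gene Mcm6 at 90.9 ± 2.10 against 32.8 ± 3.07. Of 45 MYC targets, 40 were higher in Math1+ cells and 1 in Sox2+ cells (41 when adjusted over the list alone, camera adjusted p = 1.06e-06, adjusted p = 0.397 with an estimated correlation), led by Odc1 of polyamine synthesis (log2 difference -1.20) and Dkc1 of ribosomal RNA processing (-1.03). Of 11 Sonic hedgehog targets, 10 were higher in Math1+ cells (11 passed when adjusted over the list alone, camera adjusted p = 0.00435, adjusted p = 0.397 with an estimated correlation): the WNT antagonist gene Sfrp1 (chromosome 8, 23411502 to 23449632) was 235 ± 15.3 against 15.1 ± 4.39 and Gli1 (chromosome 10, 127329882 to 127341974) 54.2 ± 4.45 against 14 ± 0.842 (log2 difference -1.88, adjusted p = 7.07e-07). The exception was Hhip, which encodes a hedgehog-binding inhibitor, at 17.8 ± 0.202 in Sox2+ and 0.3 ± 0.0737 in Math1+ cells. Of 16 granule neuron progenitor genes, 11 were higher in Math1+ cells and 3 in Sox2+ cells (14 when adjusted over the list alone, camera adjusted p = 0.066), with Barhl1 (chromosome 2, 28907679 to 28916668) at 92.4 ± 13.3 against 4.94 ± 1.73. Other genes among the lowest were the long non-coding Gm17322 (log2 difference -4.54) and the homeobox gene Tlx3 (chromosome 11, 33200752 to 33203589), at 59.9 ± 13.1 against 1.98 ± 0.674.

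Myc itself (chromosome 15, 61985391 to 61990374) was low in both normal groups, at 2.64 ± 0.0351 in Sox2+ and 0.985 ± 0.132 in Math1+ cells (0.88, adjusted p = 1.39e-05), while Mycn (chromosome 12, 12936093 to 12941914) was 26.1 ± 1.83 and 40.7 ± 9.49 (-0.60, adjusted p = 0.0133). Otx2 (chromosome 14, 48657677 to 48673819), a marker of Group 3 medulloblastoma, was 0.793 ± 0.392 and 9.11 ± 0.801 (-2.51, adjusted p = 6.24e-06), and Npr3 (chromosome 15, 11839896 to 11907287), at 0.0495 ± 0.00995 and 0.202 ± 0.0282, was too low to be tested. In lists without a camera call, the differences went both ways or rested on few genes. The 21 granule neuron differentiation genes had 12 higher and 5 lower in Sox2+ cells, with Calb2 at 2.44 and Cntn1 at 2.38, and the 20 synaptic genes 10 and 8, with Gria1 at 4.03 and Slc17a6 at -3.03. The 18 glycolysis genes had 10 higher and 7 lower (Aldoc 4.34, Pfkl 1.33), the 21 genes of the p53 pathway and cell cycle inhibitors 7 and 8 (Pmaip1 -1.38, Trp53inp1 1.07), and the 21 immediate early genes 6 and 10 (Jun -2.15, Egr2 -1.31). Few markers of other cell types were measured: 6 of 6 endothelial genes were higher in Sox2+ cells (Mfsd2a 1.55, Kdr 1.31), as were 3 of 3 fibroblast genes (Col1a2 1.55, Pdgfrl 1.41) and 2 of 5 microglia genes (Lyz2 0.68). Of 4 red blood cell genes 1 was higher (Bpgm 0.65) and 1 lower, and of 7 interferon genes 3 were higher, with Ifitm3 at 0.94 and Tapbp at 0.55, and 1 lower. The subgroup markers Tnc (4.76), Gad1 (3.52), Pdlim3 (3.93) and Rbm24 (0.51) were higher and Mab21l2 (-1.68) lower in Sox2+ cells.

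In all, 8483 of 11527 genes passed, 3925 higher and 4558 lower in Sox2+ cells, and 1859 of them differed by at least 1 on the log2 scale (1333 higher, 526 lower). Libraries of the groups did not overlap for 8956 genes (77.7%), where chance gives 10%. Median-of-ratios scaling moved the median difference of all genes from -0.051 to 0.060 and the split of passing genes to 4712 higher and 3492 lower, so small differences depend on the scaling. With 1 spread for all 4 groups, 5044 genes passed, and Rbm24, Egr2, Foxj1, Ifitm3, Lyz2, Mab21l2 and Tapbp no longer did. The call of Rbm24 also ended with a pseudocount of 0.1 (adjusted p = 0.0502) and without Normal_M4, Normal_M5, Normal_S5 or Normal_S6 (adjusted p from 0.117 to 0.138).

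Tumours were then compared with the cells they came from. SOX2 tumours differed from Sox2+ cells in higher levels of MYC targets, glycolysis genes and macrophage markers, and in lower levels of the glial, oligodendrocyte, GABAergic and stem cell genes that had marked the Sox2+ cells. None of these list calls held with an estimated correlation (adjusted p from 0.21 to 0.409). Myc was 21.1 ± 6.88 in SOX2 tumours against 2.64 ± 0.0351 in Sox2+ cells (log2 change 2.53 ± 0.27 SE, adjusted p = 1.06e-05), and Mycn fell to 0.490 ± 0.352 from 26.1 ± 1.83 (-4.22, adjusted p = 1.46e-08). Whether reads of the lentiviral Myc are part of these values is not stated. Sox2 fell to 7.07 ± 4.40 (-3.17, adjusted p = 0.000318), while Gfap, at 129 ± 85.7, varied too much between tumours to pass (0.75, adjusted p = 0.456).

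**Figure D2:**
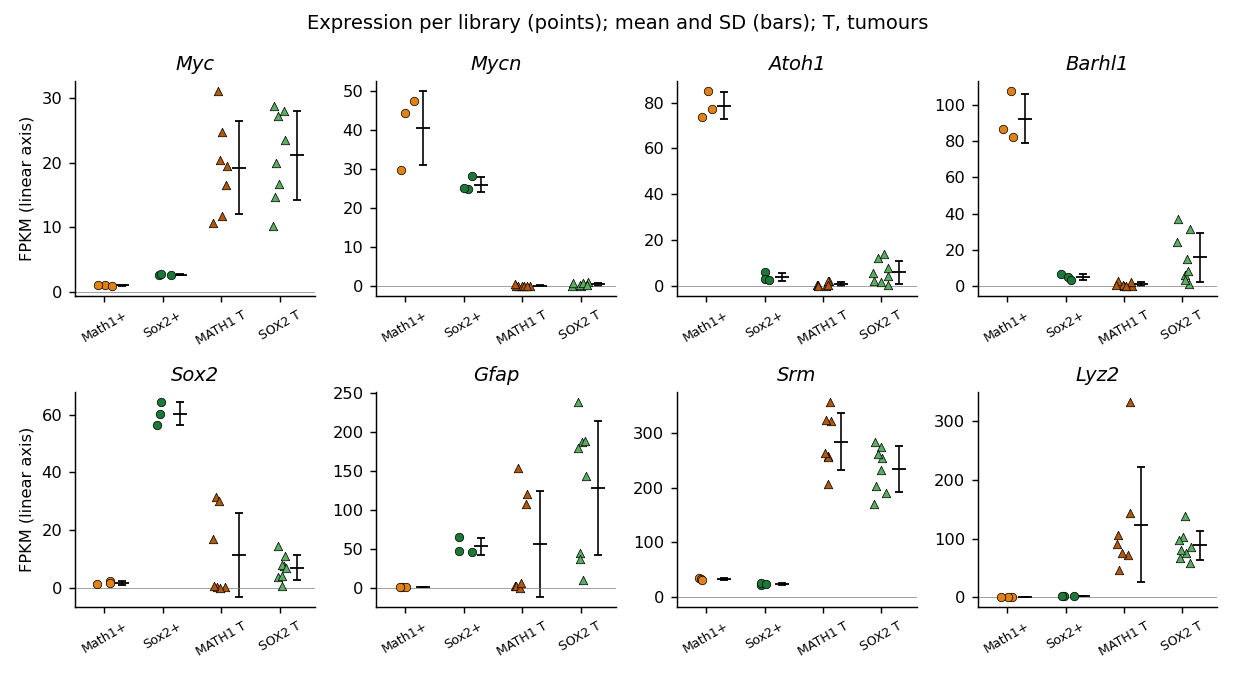
FPKM of 8 genes on linear axes, with 1 point per library and the mean ± SD beside the points of each group. Myc and Srm were higher and Mycn lower in the tumours of both origins than in their normal cells, Atoh1 and Barhl1 were near the floor in the MATH1 tumours, and Sox2 and Gfap were split among the MATH1 tumours, 3 of which had Gfap above 100 FPKM.

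Of 45 measured MYC targets, 44 rose in SOX2 tumours and 1 did not pass (44 when adjusted over the list alone, camera adjusted p = 4.58e-19, adjusted p = 0.219 with an estimated correlation). Srm (chromosome 4, 148591503 to 148594993), the gene of spermidine synthase, rose to 234 ± 41.7 from 24.0 ± 1.82 (3.21), and the nucleolar gene Gnl3 to 143 ± 30 from 18.4 ± 0.443 (2.86). Of 21 glycolysis genes, 15 rose and 2 fell (17 when adjusted over the list alone, camera adjusted p = 0.000517, adjusted p = 0.409 with an estimated correlation). Examples were lactate dehydrogenase Ldha (chromosome 7, 46841475 to 46855627) at 117 ± 12.1 against 12.8 ± 1.06 (3.08) and the lactate exporter gene Slc16a3 at 11.7 ± 6.22 against 0.261 ± 0.0964 (3.15). Of 38 proliferation genes, 18 rose and 5 fell (23 when adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.571 with an estimated correlation). Examples were cyclin Ccne1 up by 1.72 and Cenpf down by 1.08. Of 23 genes of the p53 pathway and cell cycle inhibitors, 13 rose and 3 fell without a camera call (adjusted p = 0.0937), and the 2 largest changes were falls, of the CDK inhibitor gene Cdkn2c to 1.56 ± 0.694 from 25.6 ± 1.62 (-3.42) and of Trp53inp1 (-1.85).

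Of 30 astrocyte genes 24 fell and 0 rose (24 when adjusted over the list alone, camera adjusted p = 1.83e-06, adjusted p = 0.341 with an estimated correlation). Gdf10 fell to 1.90 ± 2.57 from 250 ± 40.8 and the lipid-binding protein gene Fabp7 to 11.5 ± 7.44 from 632 ± 83.2 (-6.79 and -5.91). Of 16 oligodendrocyte genes 14 fell (14 when adjusted over the list alone, camera adjusted p = 1.31e-06, adjusted p = 0.21 with an estimated correlation). Examples were Gpr17 at -5.46 and Olig1 at -4.89. Of 15 GABAergic genes 11 fell and 3 rose (14 when adjusted over the list alone, camera adjusted p = 0.000509, adjusted p = 0.219 with an estimated correlation). An example was Lhx5 at 1.06 ± 2.78 (-6.96). Between the tumours only 9 oligodendrocyte and 7 GABAergic genes reached the filter. Several were thus tested here because of their values in Sox2+ cells, which favours a fall. Of 16 neural stem cell genes 11 fell (12 passed when adjusted over the list alone, camera adjusted p = 0.00814, adjusted p = 0.3 with an estimated correlation). An example was the paired-box gene Pax3 at -2.89. Of 7 choroid plexus and ependyma genes 5 fell (5 when adjusted over the list alone, camera adjusted p = 0.0128, adjusted p = 0.21 with an estimated correlation). Examples were Enpp2 at -2.86 and Tmem212 listed at 0 in all 8 tumours against 3.85 ± 0.488. The homeobox gene Lbx1 (chromosome 19, 45232684 to 45235812) fell to 0.0275 ± 0.0366 from 111 ± 7.79 (-6.77).

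Of 11 Sonic hedgehog targets 9 fell and 1 rose (10 when adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.269 with an estimated correlation): Hhip changed by -3.36, Gli1 by -2.82 (to 2.70 ± 5.92, adjusted p = 0.00451) and Sfrp1 by -2.12. WNT subgroup markers fell in 5 of 5 genes (5 when adjusted over the list alone, camera adjusted p = 0.00778, adjusted p = 0.219 with an estimated correlation), led by Tnc (-4.30) and Gad1 (-3.21), which are also glial and GABAergic genes. Group 3 markers had no camera call (adjusted p = 0.156), with Npr3 at 5.08 ± 3.01 against 0.0495 ± 0.00995 (2.34, adjusted p = 0.00131) beside Myc, and Otx2 at 1.81 ± 2.96 (0.28, adjusted p = 0.654). Granule neuron progenitor genes went both ways, with 3 up and 6 down of 18 (Zic4 -2.53, camera adjusted p = 0.354), and Atoh1, at 5.85 ± 4.98, did not pass (0.18, adjusted p = 0.836, -0.07 with a pseudocount of 0.1). Of 21 granule neuron differentiation genes 10 fell (Neurod2 -2.93, Cntn1 -2.05, camera adjusted p = 0.0725), and of 22 synaptic genes 10 fell and 3 rose (Gria1 -3.98, Cplx2 -2.43, camera adjusted p = 0.0641). The Group 4 marker Rbm24 rose by 2.15.

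Markers of cells that were not part of the sort moved with the tumours. Of 17 microglia and macrophage genes 17 rose (17 when adjusted over the list alone, camera adjusted p = 7.37e-07, adjusted p = 0.219 with an estimated correlation). Examples were lysozyme Lyz2 (chromosome 10, 117277331 to 117282321) at 88.5 ± 25.1 against 1.70 ± 0.244 (5.01) and complement C1qa at 30.9 ± 6.75 against 2.86 ± 1.30 (3.07). Only 5 of the 24 genes of this list reached the filter between the normal cells. Most of the 17 were thus tested because of their values in the tumours, which favours a rise in the count and in the list test. Of 23 immediate early genes 11 rose (11 when adjusted over the list alone, camera adjusted p = 0.0162, adjusted p = 0.571 with an estimated correlation). Examples were Junb at 2.95 and Atf3 at 2.29. Without a camera call, 8 of 13 fibroblast genes rose (Col6a1 3.51, Igf2 3.24), and 3 of 7 pericyte genes rose (Acta2 4.46) and 1 fell (Notch3 -2.68). Also without a call, 7 of 13 interferon genes rose (Ifitm3 3.82, Bst2 3.51), and endothelial genes went both ways (Cldn5 -2.39, Mfsd2a 1.0). Between the normal cells only 3 fibroblast and 7 interferon genes reached the filter, and too few pericyte genes for a list test. For these 3 lists, too, the filter thus favours a rise. Among the highest changes of single genes were Isyna1 (chromosome 8, 70594373 to 70597290), which makes inositol phosphate, at 60.6 ± 20.1 against 0.771 ± 0.0805 (5.05), and the transcription factor gene Sim2 (chromosome 16, 94084931 to 94127032), at 28.5 ± 14.7 against 0.00832 ± 0.0144 (4.55). The antisense gene Gm16104 (4.62) is uncertain because counting by strand is not stated.

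In all, 7971 of 12341 genes passed between SOX2 tumours and Sox2+ cells, 3943 up and 4028 down, and 2801 of them changed by at least 1 on the log2 scale. The direction of the split depended on the scaling, with 3437 up and 4622 down with median-of-ratios scaling and 4401 up and 3786 down with quantile normalization. Libraries did not overlap for 7168 genes (58.1%), where chance gives 1.21%.

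MATH1 tumours differed from Math1+ cells in a rise of MYC targets, glycolysis genes and macrophage markers, and in a fall of granule neuron progenitor genes, Sonic hedgehog targets and cell cycle genes. None of these list calls held with an estimated correlation (adjusted p from 0.19 to 0.682). Myc was 19.2 ± 7.17 against 0.985 ± 0.132 (log2 change 3.27 ± 0.28 SE, adjusted p = 9.49e-06), and Mycn fell to 0.136 ± 0.178 from 40.7 ± 9.49 (-5.18, adjusted p = 3.48e-08). Atoh1 fell to 0.610 ± 0.935 from 78.7 ± 5.90 (-5.80, adjusted p = 2.34e-06), and Barhl1 to 0.774 ± 1.08 from 92.4 ± 13.3 (-5.90, adjusted p = 2.97e-06). Gli1, the readout of hedgehog signalling, fell to 1.55 ± 1.89 from 54.2 ± 4.45 (-4.67, adjusted p = 1.45e-05).

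Of 45 MYC targets, 43 rose and 2 did not pass (43 when adjusted over the list alone, camera adjusted p = 1.64e-17, adjusted p = 0.411 with an estimated correlation). Examples were Srm at 284 ± 51.9 against 33.7 ± 1.70 (3.02) and the chaperonin gene Hspd1, 99% identical to a pseudogene over 1722 bases, at 238 ± 30 against 46.6 ± 2.31 (2.32). Of 21 glycolysis genes 15 rose and 1 fell (18 passed when adjusted over the list alone, camera adjusted p = 1.49e-07, adjusted p = 0.19 with an estimated correlation). Examples were the pyruvate dehydrogenase kinase gene Pdk1 at 3.29 and Slc16a3 at 3.03. Of 38 proliferation genes 26 fell and 1 rose (28 when adjusted over the list alone, camera adjusted p = 1.3e-05, adjusted p = 0.682 with an estimated correlation). Examples were the cell cycle transcription factor gene Foxm1 at 7.46 ± 1.90 against 28.9 ± 1.49 (-1.85) and Cenpf at -1.72. Of 16 granule neuron progenitor genes 12 fell and 0 rose (12 when adjusted over the list alone, camera adjusted p = 1.57e-05, adjusted p = 0.19 with an estimated correlation). Of 11 Sonic hedgehog targets 10 fell (10 when adjusted over the list alone, camera adjusted p = 3.04e-05, adjusted p = 0.19 with an estimated correlation). An example was Sfrp1 at 3.53 ± 5.34 against 235 ± 15.3 (-6.46). Of 22 granule neuron differentiation genes 13 fell and 3 rose (17 when adjusted over the list alone, camera adjusted p = 0.0283, adjusted p = 0.541 with an estimated correlation). Examples were the microtubule genes Stmn2 at -3.83 and Dcx at -1.88. Cdkn2c fell to 1.62 ± 1.19 from 36.0 ± 1.90 (-3.95), while 9 of the 23 genes of the p53 pathway and cell cycle inhibitors rose (Phlda3 2.42, camera adjusted p = 0.229).

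Glial genes had no camera call in MATH1 tumours. Of 22 astrocyte genes 3 rose and 3 fell over all genes tested and 0 passed when adjusted over the list alone (camera adjusted p = 0.397), with Apoe at 43.0 ± 36.6 against 4.09 ± 1.14 (2.61), Sox9 at 5.75 ± 7.35 against 28.3 ± 4.04 (-3.05) and Gfap at 56.5 ± 68.0 against 1.23 ± 0.493 (2.85, adjusted p = 0.145). Sox2 was 11.4 ± 14.5 (0.82, adjusted p = 0.596). Among 8 oligodendrocyte genes Olig2 rose to 22.2 ± 12.6 from 0.394 ± 0.186 (3.87) and Pdgfra fell (-2.39, camera adjusted p = 0.503). Of 4 GABAergic genes Lhx1 fell (-1.26) and Foxp2 rose (0.80, camera adjusted p = 0.937). Of the subgroup markers, Npr3 rose to 5.29 ± 5.38 (1.95, adjusted p = 0.0246), Eomes and Rbm24 rose by 1.86 and 1.66, and Otx2, at 6.70 ± 7.77, did not pass (-1.08, adjusted p = 0.294).

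Microglia and macrophage genes rose in 17 of 18 measured genes (17 when adjusted over the list alone, camera adjusted p = 7.78e-06, adjusted p = 0.668 with an estimated correlation). Examples were Lyz2 at 124 ± 97.3 against 0.695 ± 0.249 (5.94) and C1qa at 32.2 ± 17.1 against 1.70 ± 0.840 (3.48). Here too most of the 18 reached the filter only through the tumours, as 5 of the 24 list genes did so between the normal cells, which favours a rise. Without a camera call, 4 of 6 pericyte genes rose (Acta2 4.15, Mcam 0.89), as did 3 of 10 fibroblast genes (Col1a1 2.42, Col3a1 1.38). So did 2 of 7 endothelial genes (Mfsd2a 2.25, Egfl7 1.08). The filter again favours a rise for the pericyte, fibroblast and interferon lists, of which fewer genes reached it between the normal cells. Of 11 interferon genes 3 rose and 2 fell (Bst2 4.01, Ifitm3 3.83), and of 19 synaptic genes 1 rose (Nefh 2.78) and 7 fell (Slc17a6 -2.81). The highest changes of single genes also included metallothionein Mt1, at 122 ± 75.2 against 0.724 ± 0.266 (5.98), Isyna1, at 72.2 ± 16.0 against 1.09 ± 0.0915 (5.10), and Gm266 (4.91). The lowest included Tlx3, at 0.159 ± 0.172 against 59.9 ± 13.1 (-5.71), and Gsg1l, at 0.821 ± 0.978 against 104 ± 11.7 (-5.98). In all, 6268 of 11617 genes passed, 3047 up and 3221 down, with 1985 changed by at least 1, and libraries did not overlap for 6038 genes (52.0%), where chance gives 1.67%. Leaving out any one of Normal_M1, Normal_M4 and Normal_M5 ended the calls of Npr3, Sox9, Ifitm3, Nefh, Mcam and Acta2 (adjusted p from 0.0612 to 0.118), and leaving out Normal_M4 or Normal_M5 that of Apoe (0.0554 and 0.0507). The calls of Nefh (Math1_1006, Math1_1137), Acta2 (Math1_1005, Math1_1006) and Mcam (Math1_1004, Math1_1006, Math1_1065, Math1_1140) also ended without single tumours (adjusted p from 0.0503 to 0.0709).

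**Figure D3:**
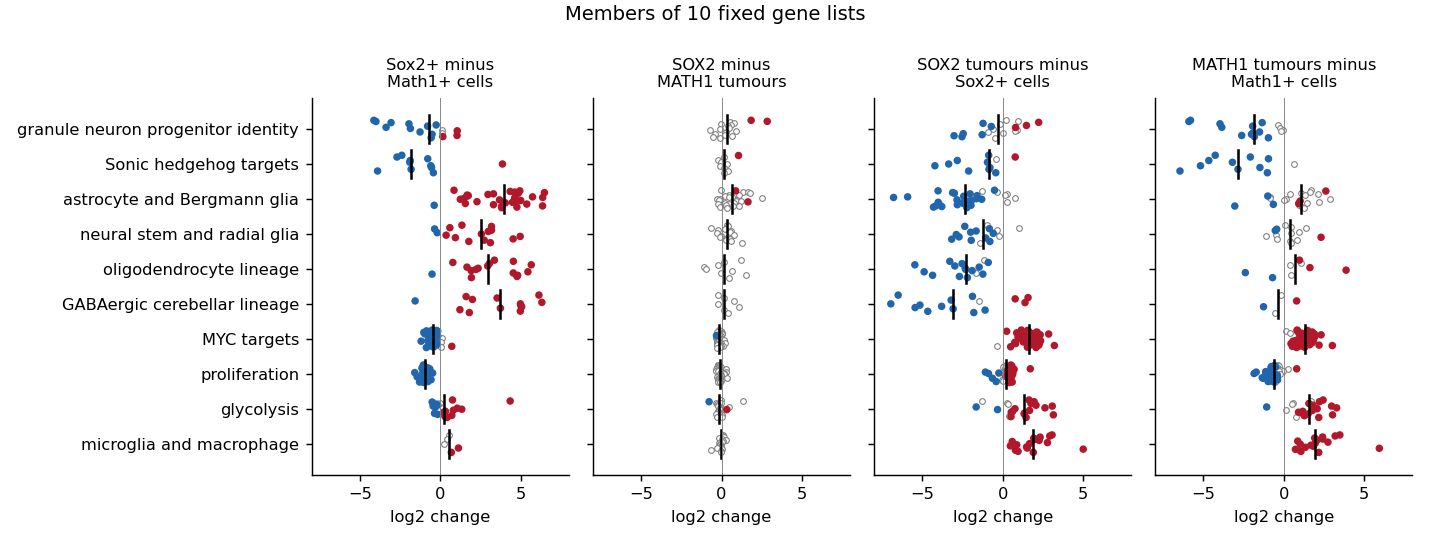
Log2 changes of the members of 10 gene lists in the 4 pairwise comparisons (filled points, adjusted p under 0.05, red higher and blue lower; open points, not passing; black bars, list medians). MYC targets, glycolysis genes and macrophage markers moved to the right in the tumours of both origins, while the median of MYC targets between the tumours was -0.154.

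The changes of both tumour types overlapped. Among 11220 genes tested in both tumour comparisons, which share no library, 2247 rose in both and 1897 fell in both, where independent lists would give 1022 and 919. With median-of-ratios scaling 2079 rose and 2150 fell. Opposite changes were found for 292 genes against 1944 for independent lists. Both comparisons set tumours grown in a host against sorted cells, so host cells and handling would move both lists alike. The excess over independent lists is therefore not a measure of change in the tumour cells alone, and Lyz2 below is a macrophage marker. Myc, Srm, Ldha, Isyna1 and Lyz2 rose and Mycn, Cdkn2c and Gli1 fell in both. Across these genes the log2 changes correlated with a Pearson r of 0.628 and a Spearman rho of 0.651, where genes are not independent replicates.

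The difference between the changes of the SOX2 and the MATH1 tumours was tested directly as an interaction, which equals the difference between the tumours minus that between the normal cells. Most oligodendrocyte and GABAergic genes had lower values in the SOX2 arm, where they had fallen, while neither list had a call in MATH1 tumours (camera adjusted p = 0.503 and 0.937). Only 8 of 16 and 4 of 18 list genes reached the filter there, so the absent calls cover a smaller set and do not show a different change. Most cell cycle genes were higher in the interaction, where 26 of 38 had fallen in MATH1 tumours and 18 had risen and 5 fallen in SOX2 tumours, a call that did not hold with an estimated correlation (adjusted p = 0.214). Lineage genes of each starting population had the largest values. Barhl1 (6.85) and Atoh1 (5.98) had changed by 0.94 and 0.18 in SOX2 tumours, which did not pass, and by -5.90 and -5.80 in MATH1 tumours. Olig1 (-6.51), Lhx5 (-6.42), Lbx1 (-6.17) and Gdf10 (-5.92) had fallen in SOX2 tumours and had low values in Math1+ cells already. Islr2 (5.33), the small GTPase gene Rab15 (5.22) and Gm17322 (5.12) completed the highest values.

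By list, 13 of 16 oligodendrocyte genes were lower in the interaction (14 when adjusted over the list alone, camera adjusted p = 1.51e-12, adjusted p = 0.0179 with an estimated correlation) and 11 of 16 GABAergic genes were lower and 1 higher (12 when adjusted over the list alone, camera adjusted p = 3.08e-08, adjusted p = 0.0399 with an estimated correlation). These were the only 2 of 39 list calls of the whole study that held with an estimated correlation. Over the members measured in each comparison, their medians were 0.156 and 0.159 between the tumours and 2.989 and 3.73 between the normal cells. Both calls thus mostly restate the difference between the normal cells. In 9 of the 118 list tests the median or mean and the test differed in sign, and 0 of these had a call. Of 30 astrocyte genes 21 were lower (24 when adjusted over the list alone, camera adjusted p = 1.51e-12, adjusted p = 0.208 with an estimated correlation), and of 16 neural stem cell genes 8 (8 when adjusted over the list alone, camera adjusted p = 0.00926, adjusted p = 0.498 with an estimated correlation). Of 38 proliferation genes 34 were higher (36 when adjusted over the list alone, camera adjusted p = 1.51e-12, adjusted p = 0.214 with an estimated correlation), as were 14 of 46 MYC targets (14 when adjusted over the list alone, camera adjusted p = 0.00135, adjusted p = 0.848 with an estimated correlation). Of 11 Sonic hedgehog targets 6 were higher and 1 lower (7 when adjusted over the list alone, camera adjusted p = 0.00189, adjusted p = 0.207 with an estimated correlation), and of 18 granule neuron progenitor genes 7 were higher (7 when adjusted over the list alone, camera adjusted p = 0.00679, adjusted p = 0.541 with an estimated correlation). Choroid plexus genes (4 of 8 lower, 4 when adjusted over the list alone) and WNT subgroup markers (3 of 5 lower and 1 higher, 5 when adjusted over the list alone) had camera adjusted p = 0.0139 and 0.0446, and both had adjusted p = 0.173 with an estimated correlation. The WNT call also ended with ranks (adjusted p = 0.0963). Glycolysis and macrophage genes had no call (adjusted p = 0.121 and 0.522).

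The interaction passed for 3875 of 13059 genes (1907 higher, 1968 lower), of which 1498 had a size of at least 1. The split depended on the scaling. It widened to 1620 higher and 2371 lower with median-of-ratios scaling and turned to 2531 higher and 1910 lower with quantile normalization. The count rose to 6730 with array weights and fell to 2549 without the Sox2+ library Normal_S5. Of 100 splits of the libraries, 5 gave at least as many genes, the real one included. The 4 others kept or mirrored the normal groups, and splits that mixed these groups gave at most 1 gene. The count thus went with the normal groups, and chance is not excluded for any part that goes with the tumour labels.

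SOX2 and MATH1 tumours were compared with each other to ask whether tumours differ by their origin. Of the genes that differed by at least 1, 51 were pseudogenes and 70 protein coding, and the largest differences were in pseudogenes. Myc was 21.1 ± 6.88 and 19.2 ± 7.17 (log2 difference 0.14, adjusted p = 0.781), and neither Sox2 (0.53, adjusted p = 0.748), Gfap (2.51, adjusted p = 0.177), Gli1 (-0.04, adjusted p = 0.979), Npr3 (0.19, adjusted p = 0.861) nor Otx2 (-1.15, adjusted p = 0.274) passed. Mycn was too low to be tested. The direction of Gli1 and Npr3 turned when single tumours were left out (Gli1 0.23 without Math1_1137, Npr3 -0.05 without Math1_1065). Atoh1 and Barhl1, the granule neuron progenitor genes, were higher in SOX2 than in MATH1 tumours, the reverse of their order in the normal cells: Atoh1 was 5.85 ± 4.98 against 0.610 ± 0.935 (1.84, adjusted p = 0.0451, a call lost with other scalings) and Barhl1 15.7 ± 13.7 against 0.774 ± 1.08 (2.84, adjusted p = 0.0132).

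The 5 highest differences were processed pseudogenes, 90.7% to 98.9% identical to a protein-coding transcript over the aligned bases and uncertain for that reason. Gm6166 (chromosome 9, 57483963 to 57484371) was 134 ± 44.2 in SOX2 and 0.350 ± 0.110 in MATH1 tumours (6.59), Rps3a3 (chromosome 13, 108670603 to 108671397) 189 ± 41.1 and 1.54 ± 0.398 (6.22), and Rps15a-ps8, Gm26983 and Gm12901 differed by 5.60, 5.54 and 5.38. The same 5 were higher in Sox2+ than in Math1+ normal cells, with Rps3a3 at 66.9 ± 0.569 against 1.19 ± 0.140. The ribosomal protein gene Rps3a1 (chromosome 3, 86137940 to 86142702), whose transcript is 98.9% identical to Rps3a3 over 795 bases, was lower, at 97.5 ± 30.8 against 261 ± 37.4 (-1.53, adjusted p = 0.00679). Ahcy (-1.39), which is near-identical to Gm4737 (99.7% over 2083 bases, 3.04), is uncertain for the same reason. Among genes without such a copy, the tubulin gene Tubb6 (chromosome 18, 67390717 to 67402749) was 16.2 ± 7.40 against 51.6 ± 23.1 (-1.63, adjusted p = 0.00655), the Ras family gene Mras 5.75 ± 1.30 against 12.1 ± 2.72 (-0.96, adjusted p = 0.00195), and mt-Nd1 (chromosome M, 2751 to 3707) 2440 ± 448 against 4820 ± 978 (-0.98, adjusted p = 0.00104). The last went with the mitochondrial share of FPKM, 7.38 ± 1.48% in SOX2 and 11.93 ± 1.01% in MATH1 tumours. Eomes, a T-box gene among the Group 4 markers, was 1.67 ± 1.19 against 6.22 ± 4.51 (-1.31, adjusted p = 0.0474).

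Of the lists, astrocyte genes were higher in SOX2 tumours as a group (camera adjusted p = 0.00553, adjusted p = 0.849 with an estimated correlation), with 2 of 28 genes passing (2 when adjusted over the list alone) and a median of 0.668. The MATH1 tumours were split in this, with Gfap at 108 to 154 FPKM in 3 and at most 7.04 in 4, against 10.4 to 239 in SOX2 tumours. MYC targets were lower by a median of -0.154 (camera adjusted p = 0.00259, adjusted p = 0.849 with an estimated correlation), with 1 of 46 passing, Hspd1, and 0 when adjusted over the list alone. The median shrank to -0.107 with median-of-ratios scaling and -0.053 with quantile normalization, and 0 genes passed with either. Hspd1 is near-identical to a pseudogene. Of the protein-coding parents of tested pseudogenes, 16.5% passed and were lower in SOX2 tumours, against 3.9% of other protein-coding genes. The list was not tested without such parents. Granule neuron progenitor genes had 2 of 18 passing (6 when adjusted over the list alone, camera adjusted p = 0.0623), Sonic hedgehog targets 1 of 9 (1 when adjusted over the list alone, camera adjusted p = 0.294), and proliferation 0 of 38 (0 when adjusted over the list alone, camera adjusted p = 0.0623). Macrophage markers did not differ as a list (0 of 18, camera adjusted p = 0.992).

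In the test of SOX2 tumours against MATH1 tumours, 732 of 11960 genes passed, 260 higher and 472 lower in SOX2 tumours, and 129 of them differed by at least 1 (116 higher, 13 lower). Of the 116, 51 were pseudogenes, and without pseudogenes and their parents 574 genes passed. Libraries did not overlap for 197 genes (1.65%), where chance gives 0.0311%. Median-of-ratios scaling turned the split to 343 higher and 280 lower, with 623 passing. The count was 454 without the filter, 1561 with array weights, 1693 with all 4 groups in 1 fit and 1176 without Sox2_727 and Math1_1065. It was 398 without Sox2_631, 421 without Sox2_752, 481 without Math1_1004, 447 without Math1_1006 and 1159 without Math1_1065. The calls of Atoh1 and Eomes ended with median-of-ratios scaling (adjusted p = 0.0502 and 0.0517), that of Atoh1 with quantile normalization (0.0628) and that of Eomes with a pseudocount of 0.1 (0.0521). They also ended without any one of Sox2_631, Sox2_682, Sox2_750, Sox2_752, Sox2_1017, Math1_1006, Math1_1137, Math1_1139 and Math1_1140 (adjusted p from 0.0547 to 0.0915), that of Atoh1 without Sox2_598 (0.0508) or Math1_1004 (0.0855) and that of Eomes without Sox2_727 (0.0663) or Sox2_728 (0.0607).

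The difference between the normal cells was then followed into the tumours. Between the normal cells, 1422 genes tested in both comparisons passed with a difference of at least 1. Of these, 79 (5.56%) passed in the tumours in the same direction and 15 (1.05%) in the opposite one. Permuted tumour labels gave at most 31 and 3 in 100 draws, with a median of 0 in the same direction. Both counts lay above the draws, which shows that the tumours differed but does not test whether the normal difference was kept. Of all genes tested between the tumours, 6.12% passed in either direction. Of the 79, 32 were pseudogenes and 40 protein coding, and 71 were higher on the Sox2 side. Of all 129 passing genes that differed by at least 1 between the tumours, 116 were higher in SOX2 tumours. Among the protein-coding genes, chosen after their values were seen, were the transcription factor genes Tfap2b (49.7 ± 1.37 in Sox2+ and 0.308 ± 0.0948 in Math1+ cells, 7.31 ± 5.90 in SOX2 and 0.00262 ± 0.00328 in MATH1 tumours) and Tfap2a (45.7 ± 0.741, 0.266 ± 0.0262, 7.08 ± 3.97 and 0.521 ± 1.32), and the GABA transporter gene Slc6a11, with a difference of 5.05 between normal cells and 1.84 between tumours. The median difference of the 1422 genes was 1.5 in normal cells and 0.155 in tumours in the same direction. Across 10559 genes the differences correlated with a Pearson r of 0.289 and a Spearman rho of 0.200, genes not being independent replicates, and 30 of 100 permutations of the tumour labels gave an r of at least that size (range -0.442 to 0.380). Without pseudogenes and their parents 40 genes were kept. The count was 41 without Normal_S4, 37 without Normal_S5, 43 without Normal_S6 and 124 without Math1_1065.

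**Figure D4:**
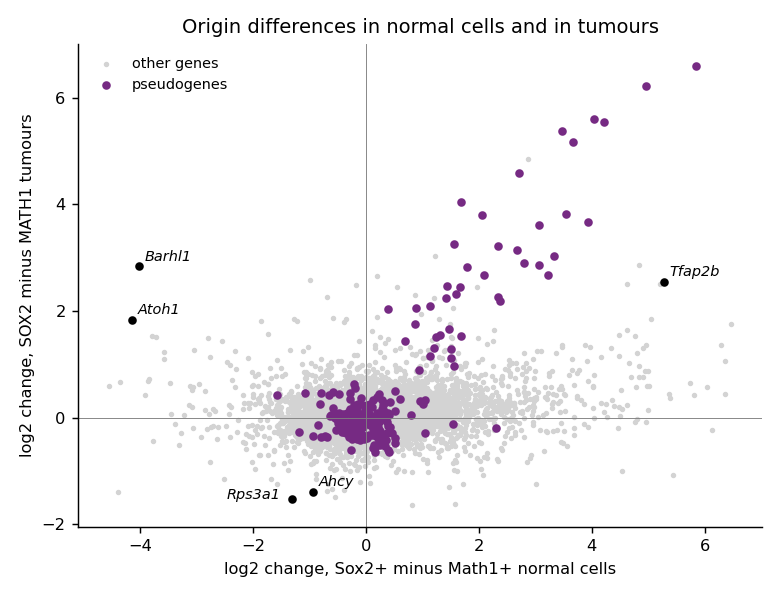
Difference between the tumours against difference between the normal cells, 1 point per gene (purple, pseudogenes; black, 5 genes named in the plot). Pseudogenes with large differences lay along a rising line and the others near 0, Barhl1 and Atoh1 at the upper left, and most other genes near 0 on the tumour axis.

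Tumours were more alike within than between origins by a small margin. The mean correlation between tumours of the same type was 0.934 and between types 0.914, over 11960 genes, a difference of 0.0199 (two-sided exact permutation test over 6435 splits, p = 0.0028). For 15 of 15 tumours the nearest tumour was of the same type. The difference was 0.0129 without pseudogenes and the parent genes of tested pseudogenes, which separated the libraries by origin for reasons left open (similarity of tumours, exact permutation test, p = 0.0255). The nearest tumour of Math1_1005 and Math1_1006 was then a SOX2 tumour. The ranges overlapped, at 0.888 to 0.976 within SOX2, 0.855 to 0.967 within MATH1 and 0.854 to 0.956 between types.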

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

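The tests of strain, of parents lower for another reason, of host tissue and of host astrocytes were chosen only after the results were seen; the tests of read sharing and of other splits of the libraries were written before, except the demand that the summed reads do not differ, which was added after.

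Single tumours stood apart from the other tumours of their group in 30 of 217 groups of values of named genes. About 1 in 20 (5%) would by chance if the values were normal and independent. Values near the floor and genes that vary together are not, so the share is no test of an excess. The measure is the gap to the nearest other tumour as a share of the group's range on the log2(FPKM + 1) scale, and 9 of the 30 belonged to Sox2_727. In that tumour Gad1 (gap 0.924, 6.91 FPKM against at most 0.184), Gria1 (0.904), Lhx5 (0.81, 7.94 FPKM against at most 0.515), Bpgm (0.571), Ccne1 (0.53) and Notch3 (0.528) were highest, and Sim2 (0.646, 1.89 FPKM against 18.0 to 52.5), E2f1 (0.558) and Egfl7 (0.531) lowest. In Sox2_598 Gli1 (0.714, 17.3 FPKM against at most 1.63), Otx2 (0.663, 9.04 against at most 1.6) and Gpr17 (0.573) were highest. In Sox2_631 Rps3a1 was lowest (0.886, 23.1 FPKM against 97.1 to 116) and Rps3a3 highest (0.723, 289 against 160 to 188). In Sox2_682 Jun was highest (0.649) and Lhx1 lowest (0.621).

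Among the MATH1 tumours, Math1_1005 was highest for Tmem212 (1.0, 0.0933 FPKM, listed at 0 in the other tumours) and Tnc (0.582). Math1_1006 was highest for Lhx5 (0.892), Gad1 (0.889) and Igf2 (0.68, 55.3 FPKM against at most 3.47). Math1_1137 was highest for Mycn (0.726), Foxm1 (0.63) and Gli1 (0.587) and lowest for Mab21l2 (0.591). Math1_1140 was highest for Enpp2 (0.668), Gpr17 (0.643) and Pdgfra (0.599), Math1_1139 for Lbx1 (0.634, but only 0.253 FPKM) and Math1_1065 for Tapbp (0.591).

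The tumour against normal changes differed between the origins, by the interaction test, for 3875 genes. Among the highest values were those of Barhl1 (6.85), Atoh1 (5.98), Islr2 (5.33), Rab15 (5.22) and Gm17322 (5.12), and among the lowest those of Olig1 (-6.51), Lhx5 (-6.42), Lbx1 (-6.17) and Gdf10 (-5.92). Of 100 splits of the libraries 5 gave as many genes, the real one included, with 4396 as the highest of the others. Chance is therefore not excluded for any part of this count that goes with the tumour labels. Of the 99 other splits, 18 kept or mirrored the normal groups and gave 3037 to 4396 genes, and the others gave at most 1, which points to the difference between the normal groups as the structure behind the count. Between SOX2 and MATH1 tumours the real split was the only 1 of 100 as large (732 genes, highest other 555). So it was for SOX2 tumours against Sox2+ cells (7971, highest other 54) and for MATH1 tumours against Math1+ cells (6268, highest other 552). This makes chance unlikely for these counts without excluding it, since not all splits were drawn. The count between the tumours ran from 398 to 1159 without single libraries, at its lowest below the highest other split. For Sox2+ against Math1+ cells (8483, highest other 0) the 10 splits are too few for a share under 0.05, with 1 as large.

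Copies of other genes separated the SOX2 from the MATH1 libraries: 57 pseudogenes were higher and 6 lower in SOX2 tumours, and 37 of the 38 also tested in the normal cells were higher in Sox2+ cells. The 42 tested parents of the higher copies were lower in SOX2 tumours by a median of -0.212 (bootstrap interval -0.312 to -0.147). Reads of the parents counted on the copies would lower them, but by a median of -0.091 only, since the copies held a median of 6.79% of the summed reads in SOX2 and 0.415% in MATH1 tumours. The summed reads still differed, by a median of -0.082 (-0.141 to -0.02), so read sharing alone leaves part of the parents' difference unexplained, and transcription of the copies alone leaves all of it. Transcription beside parents that are lower for another reason stays open: at these shares it would raise the sum too little for the limit of 0.3 set beforehand to be reached. Read sharing would make the parents with the most copy reads the lowest, and the correlation left this undecided (Spearman rho -0.15, bootstrap interval -0.531 to 0.219). The higher copies lay on 17 chromosomes, which few linked regions would not give but which a difference in strain throughout the genome may give. For the copies as a set, strain, transcription and alignment or counting cannot be told apart, because all go with the cells' origin. Within the SOX2 tumours, Sox2_598 and Sox2_631 had the lowest Eno1 (21.5 and 20.5 FPKM) and Ahcy (2.06 and 1.31). They had the highest of the near-identical Eno1b (57.2 and 51.1) and Gm4737 (16.1 and 10.8). Sox2_631 had low Rps3a1 (23.1) beside high Rps3a3 (289), which Sox2_598 did not (97.1 and 169). Origin alone does not give these differences, but the pairs were picked after their values were seen. A biological difference between cells of Sox2+ and Math1+ origin in single parent genes was not tested apart from these explanations.

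Astrocyte genes were high in 3 of the 7 MATH1 tumours: Gfap was 154, 120 and 108 FPKM in Math1_1005, Math1_1006 and Math1_1065 and at most 7.0 in the other 4, and Sox2 was 31.4, 30 and 16.8. The split was not of astrocyte genes alone: in the same order, Acta2 was 79.4, 90.5 and 652 against at most 6.38, Col6a1 25.9, 11.6 and 22.3 against at most 3.09, Foxj1 31.2, 8.13 and 32.6 against at most 0.353 and Ifitm3 118, 87.9 and 362 against at most 8.42. Host cerebellar tissue with its neurons in the tumour piece is argued against, because Gabra6 and Pcp2, abundant in mature granule and Purkinje cells, reached at most 0.16 FPKM in these 3 tumours. Host astrocytes may still be the source of the astrocyte genes. The lowest Sox2 to Gfap ratio of the 3 tumours (0.16) lay above the highest of the SOX2 tumours (0.11). This does not exclude 1 shared profile of host astrocytes, because Sox2 or Gfap of tumour cells would enter the ratio of a whole tumour. Host astrocytes of another state stay open too. Host astrocytes and an astrocyte-like state of tumour cells cannot be told apart, because no label separates host from tumour cells, and other host cells were not tested. No biological explanation was tested, since the design puts all 7 in 1 group.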

How the results depend on the processing

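Fits without pseudogenes and their parents and fits without Sox2_727 and Math1_1065 were chosen only after the results were seen. Counts under the alternatives not given below stayed within 1.5 times the reported count. The causes of the following moves were not tested, except that a minimum log2 change of 1 counts fewer genes by construction. With that minimum, 1859 genes passed between the normal cells, 129 between the tumours, 2801 for SOX2 tumours against Sox2+ cells, 1985 for MATH1 tumours against Math1+ cells and 1498 for the interaction. With all 4 groups in 1 fit, 5044 genes passed between the normal cells and 1693 between the tumours. Array weights gave 1561 between the tumours and 6730 for the interaction, no filter gave 454 between the tumours, and leaving out Sox2_727 and Math1_1065 gave 1176. The normal difference was kept for 40 genes without pseudogenes and their parents. The correlation of the normal with the tumour difference was 0.345 with a pseudocount of 0.1, 0.235 with no filter and 0.228 without pseudogenes and their parents. Of 39 list calls 2 held with camera with estimated correlation, and ranks gave 48. With the shared title numbers as a replicate block, 7960 genes passed between the normal cells, although the pairs with a shared number were no more alike than others (r of 0.0291 and -0.0372 against -0.0298 to 0.0315).

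Leaving out each library in turn gave 6831 to 8124 genes between the normal cells, 398 (without Sox2_631) to 1159 (without Math1_1065) between the tumours, 6166 to 8215 for SOX2 and 4592 to 6481 for MATH1 tumours against normal cells, and 2549 (without Normal_S5) to 4220 (without Math1_1139) for the interaction. It gave 3274 to 4300 genes changed in both tumour types, 37 (without Normal_S5) to 124 (without Math1_1065) kept genes, a correlation of 0.206 (without Normal_S6) to 0.346 (without Math1_1065) and a similarity difference of 0.0166 to 0.0235.

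Of the tests of genes that met the rule for naming, 2388 kept direction and side of the threshold, 67 no longer passed and 12 turned direction, none of which had passed in the reported test. Atoh1 in SOX2 tumours against Sox2+ cells (0.18) was -0.07 with a pseudocount of 0.1 and -0.04 (without Sox2_1017) to 0.50 (without Sox2_727) without single libraries, -0.01 without Normal_S6 and -0.02 without Sox2_750. Otx2 in the same comparison was -0.04 (without Sox2_598) to 0.45. Between the tumours Gli1 was -0.48 (without Sox2_598) to 0.23 (without Math1_1137) and Npr3 -0.05 (without Math1_1065) to 0.49. Depth limits genes of low value: 1 FPKM of a gene of 2 kb stood for as few as 25.4 reads, and log2(FPKM + 1) understates their change.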

Other observations

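The genes in the next paragraph and the test of sex were chosen only after the values were seen.

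Single genes known from muscle were higher in SOX2 than in MATH1 tumours, and no list of skeletal muscle genes was tested. The pericyte and smooth muscle list (median 0.381) and the fibroblast list (0.429) both had a camera adjusted p of 0.0623, and with ranks of 0.0454 and 0.0352. With an estimated correlation both had an adjusted p of 0.849, and 1 of 8 and 0 of 13 members passed. Acta1, skeletal muscle actin, was 61.8 ± 60.0 against 2.74 ± 2.85 FPKM (log2 difference 3.44, adjusted p = 0.0338), the myosin gene Myh7b 10.1 ± 6.18 against 0.97 ± 0.424 (2.29, adjusted p = 0.00153) and desmin Des 8.63 ± 7.84 against 0.764 ± 0.62 (2.01, adjusted p = 0.0281). Ckm, Klhl41, Cox6a2, Mylpf and Tnni1 differed by 2.34, 2.22, 2.18, 2.13 and 1.69. The tumours were not alike in this: Acta1 was 0.669 in Sox2_727 and 3.84 in Sox2_728, below the 7.42 of Math1_1004. Of single neuronal genes, the sensory neuron factor Pou4f1 was 13.3 ± 5.92 against 2.25 ± 2.26 (2.23, adjusted p = 0.00945), the neuropeptide gene Adcyap1 11.3 ± 8.06 against 0.794 ± 1.22 (2.58, adjusted p = 0.0119) and Stmn2 25.5 ± 16.9 against 4.31 ± 3.81 (2.26, adjusted p = 0.0309). Synapse genes as a list did not differ (0 of 18 passing, median -0.027, camera adjusted p = 0.749). The granule neuron differentiation list, which includes Stmn2, had 1 of 20 passing and a median of 0.233. Its camera adjusted p was 0.0623, with ranks 0.0301 and with an estimated correlation 0.849. The imprinted H19 reached 935 FPKM in Sox2_727 and 184 in Math1_1006, Hbb-bs 142 in Sox2_727, and Acta2 652 in Math1_1065. No explanation of these values was tested.

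Transcripts that tell the sexes apart were split between the tumours. As a share of Xist and the Y-linked Eif2s3y, Xist took 66.9% to 95% in the normal cells, under 10% in 7 of the 15 tumours and over 95% in 5. The 7 were 5 of the 7 MATH1 and 2 of the 8 SOX2 tumours, so sex partly went with the comparison of the tumours. Sox2_728 (90.2%) and Sox2_1017 (94.7%) lay within the normal range, and Sox2_750 lay below it at 35.5%. Cells of both sexes in the mix of the normal sorts are argued against for the 7 tumours under 10%. A candidate explanation for these 7 is growth from donor cells of 1 sex; it does not cover Sox2_750, and the mix stays open for Sox2_728 and Sox2_1017. Host cells of a given sex stay open as well, because the sex of donors and hosts is not given in the sources used here.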
